A study of Homo sapiens with 4 samples.

How the data were processed

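Chromatin-bound nascent RNA was measured in 4 samples of K562 cells, 2 with wild-type SF3B1 and 2 with SF3B1 K700E, harvested 4 days after induction with doxycycline at 1 µg/ml, per the labels. Per the labels' protocols, chromatin was isolated in the presence of α-amanitin, its RNA was depleted of polyadenylated and ribosomal RNA, and an adapter was ligated to RNA 3′ ends before cDNA was made by template switching and amplified by PCR for long-read sequencing. The submitters' processing notes name cutadapt, minimap2 and the hg38 build; tool versions and settings are not given in the sources used here. The library protocol adds no molecular identifiers that the labels mention, so reads that share a molecule by PCR cannot be told apart and intervals cover counting error only.

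For each sample the authors deposited 2 tables. In the first, each row is an annotated intron, named by transcript, number, start and strand, with 2 deposited read counts, not normalized: reads over the intron and reads with its splice junction. The same table gives their ratio, CoSE, which the authors rounded to 2 decimals; it equals the ratio of the deposited counts within 0.005 in every row. How reads were assigned to introns is not given in the sources used here. The ratio exceeds 1 in 2.23 to 4.16% of rows. The second table gives, per row of at least 11 RNA 3′ ends, deposited values of their mean, median, smallest and largest position as a fraction from 0 to 1, their standard deviation and variance (other units) and their count. The rows of that table bear no identifiers, and the feature spanned by the fraction is not given in the sources used here. The planned distances in nucleotides, shares within fixed distances and matching of rows between samples were therefore not computed. The mutant samples' tables carry in-file labels numbered differently from their titles (MUT2 and MUT3); samples were taken as the series records assign them.

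Rows were placed on GENCODE 29 (GRCh38, the build of the files) by transcript, intron number, start and strand, which placed 87.3 to 87.6% of rows; 99.2 to 99.3% of rows start at an intron start of that release. Rows not placed were left out because their end is unknown. Rows for the same intron coordinates were counted once, with the highest count where transcripts disagreed (103 to 142 introns per sample). Gene symbols came from the reference name table. Unspliced reads were taken as reads over the intron minus junction reads, and ratios above 1 were set to 1. A read spliced to a site that the annotation lacks counts as unspliced in these tables. Junction reads were matched with some tolerance: of introns with a shared 5′ splice site whose 3′ splice sites lie 1 to 7 nt apart, 98.7% of pairs had identical junction counts, against 0% at 12 to 30 nt, so sites closer than about 12 nt are not resolved. Overlapping annotated introns share reads, and one read over several introns counts once in each.

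Efficiency per intron was tested with edgeR 4.0.16 in R 4.3.3, with spliced and unspliced counts as paired columns, 1 coefficient per sample, 1 for spliced against unspliced and 1 for its interaction with genotype, on introns with at least 10 reads in every sample. Introns spliced in all reads or in none of every sample carry no contrast and were not tested, which left 5093 of 6141. The plan fixed edgeR's quasi-likelihood F test but not its dispersion. With the default, an estimated negative binomial dispersion, 1 intron passed in the real data. Simulated counts with 100 introns changed by a log2 odds ratio of 4 and 100 by 2 then showed that this fit called 0 of either, over 4773 introns. A dispersion of 0, where the quasi-likelihood term alone carries the replicate spread, called 32% of introns changed by 4 and 2% of those changed by 2, and 0 unchanged introns. With it, the p-values per intron were in effect those of a chi-square with 1 degree of freedom. The spread was thus pooled over introns, and an intron's own scatter between replicates hardly entered its p or standard error. The dispersion of 0 was chosen on these simulated calls, after the default result had been seen. Every simulated intron had the same overdispersion between replicates (0.0503), while real introns differ in spread. The 0 unchanged introns called therefore do not show how often this fit calls unchanged introns in the real data. The simulated genes below also had 1 common spread. Several other fits, among them a likelihood ratio test and Fisher's exact test on pooled reads, were tried on simulated counts and set aside. Their simulated calls are not given here. For genes the estimated dispersion was kept: over 4889 simulated genes it called 74% of those changed by a log2 odds ratio of 4, 8% of those changed by 2 and 3 unchanged genes, against 9 unchanged genes with a dispersion of 0. For nascent reads, over 2502 simulated genes, it called 92.2% of genes changed by 4 on the log2 scale, 37.7% of those changed by 2 and 6 unchanged genes. Standard errors of log2 values were taken as the estimate divided by the square root of F.

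Nascent reads per gene were the reads over the intron of a gene with the highest total, which summed to 147291 and 122011 in WT and 47500 and 89373 in K700E, filtered with filterByExpr, scaled with TMM and tested with edgeR's quasi-likelihood test with an estimated dispersion. Correlations of log CPM across genes between libraries lay between 0.384 and 0.612: the WT libraries correlated at 0.517 and the K700E libraries at 0.550, WT 2 at 0.568 and 0.612 with the K700E libraries and WT 1 at 0.384 and 0.427, so WT replicates agreed less with each other than WT 2 did with K700E. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), on log2 of spliced over unspliced counts with a pseudocount of 0.5 and on log CPM (counts scaled to library size). P-values across introns, genes and lists were adjusted by Benjamini-Hochberg, two-sided, at 0.05. Sample means were compared by exact permutation tests in SciPy 1.17.1, whose smallest p for 2 against 2 samples is 0.333. Wilson intervals have a 95% level, and a count of 0 was given a limit of 3 counts. Figures were drawn with matplotlib 3.10.9. No 2 libraries held the same values: the chi-square of reads over introns per degree of freedom was at least 3.05 for every pair.

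The 12 gene lists, the tests and the rule for named items were fixed before the data were examined: SF3B1 cryptic targets, spliceosome, transcription elongation, replication stress and DNA damage, chromatin modifiers, ribosomal proteins, haem and erythroid genes, snoRNA hosts, mitosis, oxidative phosphorylation, epithelial markers and other blood markers. The rule named the 8 introns with the smallest p in each direction, 1 per gene, the 6 genes per direction for efficiency and 5 for nascent reads, the 4 smallest p of each called list, the 3 smallest p of 5 lists, and SF3B1. The further ADGRV1 introns, PTPRC and the upstream splice sites were chosen after their values were seen. Alternatives were other read minimums, DESeq2 1.42.0, limma on the fraction, Fisher's exact test, the replicate number as a block, other summaries and each sample left out. The upstream splice site of 1 listed gene is not reported here and was left out of that comparison. Introns were not classed as U12-type and no splice site sequence was used, as no genome sequence was used here.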

Results

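K562 cells, an established chronic myeloid leukaemia line, were induced with doxycycline to express SF3B1 either as wild type (WT) or with the K700E substitution. SF3B1 is the subunit of the U2 small nuclear ribonucleoprotein that contacts the branch point region of the intron, and K700E is a recurrent substitution of that protein in myeloid neoplasms. RNA bound to chromatin, depleted of polyadenylated and ribosomal RNA, was read with PacBio long reads from 2 WT and 2 K700E samples. The comparison asked how far introns had been removed from RNA still being transcribed, and where RNA polymerase II stood, in mutant against wild-type cells. Over unique annotated introns, the WT samples held 1346733 and 1185006 read-intron overlaps and the K700E samples 459681 and 909621, so that K700E replicate 1 was the shallowest. Introns with at least 10 reads numbered 34512 and 30684 in the WT samples and 7717 and 25166 in the K700E samples. Co-transcriptional splicing efficiency (CoSE) is the share of reads over an intron that carry its splice junction. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. In the test per intron that spread is pooled over introns, so an intron's own scatter hardly enters its p.

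Transcripts of ADGRV1, which encodes a very large adhesion G protein-coupled receptor of inner ear and retina, carried the annotated junction of 3 introns less often in K700E cells. A read spliced to a site that the annotation lacks counts as unspliced in these values. Intron 27 (chromosome 5, 90681455 to 90683585, hg38, plus strand, between exons of ENST00000405460) was spliced in 95.1% ± 3.51 of reads in WT and 42.0% ± 10.2 in K700E (SD, n = 2 each). Intron 36 (90704489 to 90705399) went from 87.4% ± 5.57 to 37.2% ± 9.90, and intron 24 (90675446 to 90676079) from 99.9% ± 0.192 to 84.1% ± 0.692. Adjusted p-values in edgeR's quasi-likelihood test were 5.27e-09, 0.000142 and 0.00394, and efficiency was lower in both K700E samples than in both WT samples at all 3 introns. Such a separation was seen at 19.9% of all 5093 introns tested, against 16.7% by chance, so it does not by itself mark these introns out. Without K700E replicate 2 intron 27 differed by -45.9 percentage points (adjusted p = 0.279). The log2 odds ratios were -4.81 ± 0.68, -3.64 ± 0.68 and -6.52 ± 1.40 (standard error). As a long read over several introns counts once in each, the 3 introns may share reads and are not independent. For intron 27 the 95% Wilson intervals were 94.7 to 98.9% and 88.1 to 95.4% in the WT samples, from 244 and 202 reads. In the K700E samples they were 37.1 to 61.4% and 24.6 to 46.6%, from 61 and 69 reads. Of the 64 non-overlapping ADGRV1 introns with at least 10 reads in every sample, the other 61 had a median difference of 0.0 percentage points (quartiles -2.59 and 2.97), 10 lower and 5 higher in both K700E samples than in both WT samples. One of these, the ADGRV1 intron from 90690959 to 90692604, stood at 81.5% and 75.2% in WT and 63.6% and 60.7% in K700E. Its difference of -16.2 points is as large as that of intron 24, but it did not pass (22 and 28 reads in K700E; edgeR adjusted p = 0.986); it was singled out after its values were seen.

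**Figure D1:**
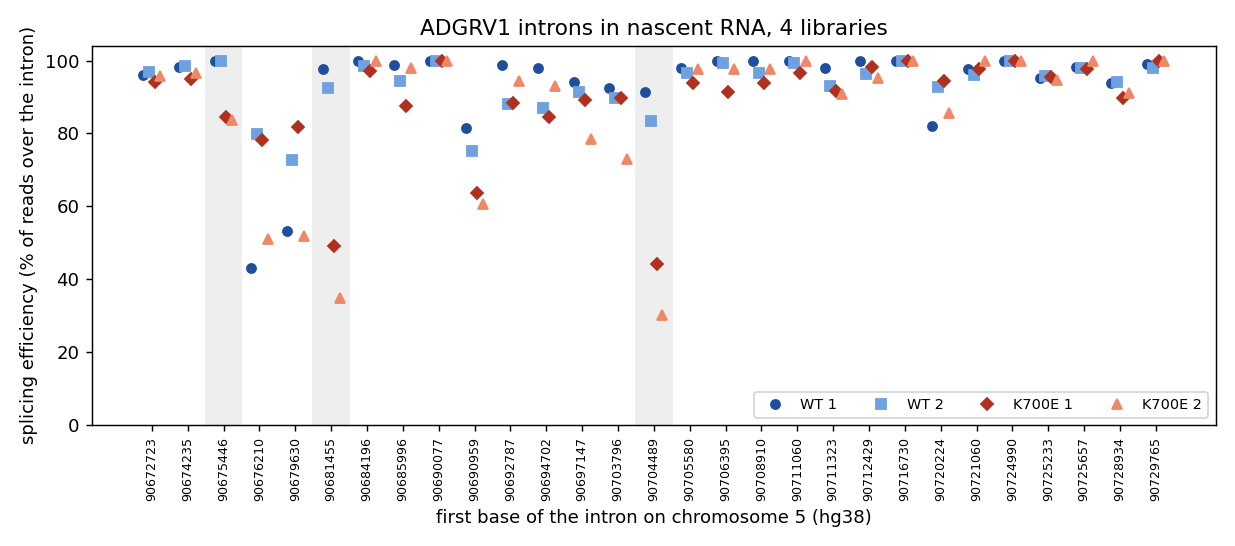
Splicing efficiency (vertical axis, percent of reads over the intron) of ADGRV1 introns from 90672723 to 90729765, in transcript order (horizontal axis, first base on chromosome 5), 1 point per library, with the 3 introns that passed the test on grey. At 90681455 the K700E libraries stood at 49.2% and 34.8%, against 97.5% and 92.6% in the WT libraries.

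The nuclear non-coding RNA MALAT1 and MAT2A, which encodes the catalytic subunit of methionine adenosyltransferase, gave the other calls. An annotated intron of 243 nt within MALAT1 (chromosome 11, 65502394 to 65502636, plus strand, ENST00000508832) was spliced in 1.39% ± 0.566 of WT reads and 13.5% ± 7.42 of K700E reads (n = 2 each), with an edgeR adjusted p of 1.11e-10. Without K700E replicate 2 its difference of 12.2 percentage points was 6.90 (edgeR adjusted p = 0.279). Its junction reads were 218 and 151 in WT and 225 and 326 in K700E, while all reads over it were 22085 and 8446 in WT and 2714 and 1735 in K700E. Read-intron overlaps over all MALAT1 introns were 83554 and 38970 in WT and 17085 and 30256 in K700E. Over all of these, efficiency was 1.02% and 1.26% in WT and 4.50% and 2.99% in K700E. The K700E samples stood in the reverse order at this intron, 8.29% and 18.8%. These values do not tell RNA still being transcribed from finished MALAT1 RNA. MAT2A intron 6 (chromosome 2, 85542374 to 85542564, plus strand) passed with an adjusted p of 0.0300, but its values were 59.5% and 97.1% in WT and 87.9% and 46.8% in K700E. The replicates of MAT2A overlap between the groups, so its difference of -10.9 percentage points does not exceed the spread between replicates, and it turned to 7.86 without WT replicate 2 and 9.58 without K700E replicate 2.

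Across the 5093 introns tested, 4 had lower and 1 had higher efficiency in K700E at a false discovery rate of 0.05, and 154 had an unadjusted p under 0.05. The 154 are a smaller share than the 0.05 expected of uniform p-values, so they show no excess. The fit behind these calls held the negative binomial dispersion at 0, a choice made on simulated counts after the result of the default fit had been seen. Those simulated counts had the same spread at every intron, unlike the real ones. With an estimated dispersion 1 intron passed (ADGRV1 intron 24), and with DESeq2 or limma 0 passed. Without K700E replicate 2 the count was 0, without K700E replicate 1 it was 2 and without WT replicate 2 it was 10.

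No other named intron passed as reported. Among introns with lower efficiency in K700E, those of TFRC, the transferrin receptor, and ACTB, cytoplasmic actin, stood at 78.8% ± 0.607 against 48.0% ± 4.74 and at 70.8% ± 13.1 against 44.2% ± 8.25 (n = 2 each). An intron of the coatomer subunit gene COPA stood at 99.5% ± 0.693 against 75.3% ± 6.66 and one of NBAS at 96.3% ± 1.505 against 67.6% ± 22.3. The ACTB difference of -26.7 points was -17.4 without WT replicate 1, and the NBAS difference of -28.7 was -12.9 without K700E replicate 1 and -44.4 without K700E replicate 2. Introns of EEF1A1, a translation elongation factor, and DDX17, an RNA helicase, differed by -12.7 and -11.9 percentage points; that of EEF1A1 (94% ± 8.49 against 81.3% ± 2.87) was -6.69 without WT replicate 1, and passed at -18.7 without WT replicate 2 (edgeR adjusted p = 0.000562). The edgeR adjusted p-values of these 6 lay between 0.402 and 0.904. Among introns with higher efficiency, one of CHD2, a chromatin remodeller, stood at 44.2% ± 14.7 in WT and 84.7% ± 11.96 in K700E (adjusted p = 0.115). One of TOP2A, DNA topoisomerase II alpha, stood at 41.1% ± 28.3 and 80.0% ± 5.05 (adjusted p = 0.0992), 18.9 points higher without WT replicate 1. In edgeR both passed with ratios above 1 left out (adjusted p = 0.0406 for CHD2 and 0.0390 for TOP2A) and without WT replicate 2 (0.0199 and 0.00403), and CHD2 also at 20 reads (0.0265), while DESeq2 and limma called no intron. The RNA-binding protein genes HNRNPK and HNRNPA2B1 had introns 43.1 and 14.0 percentage points higher, with a WT spread (SD) of 33.3 points in HNRNPA2B1, whose difference turned to -9.60 without WT replicate 1 and passed at 37.5 without WT replicate 2 (edgeR adjusted p = 0.00111). Introns of ATAD2, HELZ and the pseudogene ZNF731P were 49.1, 29.9 and 56.5 percentage points higher, from as few as 10 reads per sample, with adjusted p-values from 0.970 to 0.986; HELZ was 18.2 points higher without WT replicate 1.

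Summed over the introns of a gene, no gene passed. The gene values are shares of read-intron overlaps, in which a read counts once for each intron it covers. They therefore also depend on which introns each library covered, and few reads can lie behind many overlaps. Of 4895 genes tested, 0 passed in edgeR's quasi-likelihood test and 164 had an unadjusted p under 0.05, while DESeq2 called 1 gene (MYO1C), limma 0 and Fisher's exact test on pooled reads, which compares these libraries only, 991. The 164 are a smaller share than the 0.05 expected of uniform p-values. MYO1C, an unconventional myosin, had the smallest p: 86.6% ± 2.84 of its read-intron overlaps were spliced in WT and 12.6% ± 6.06 in K700E (SD, n = 2 each, edgeR adjusted p = 1.00, DESeq2 adjusted p = 0.0127). Its overlaps numbered 44 and 13 in WT and 96 and 71 in K700E, and few reads may lie behind them. LAMB2, a laminin chain, followed with 82.0% ± 2.40 and 28.5% ± 4.35. AGO2, an Argonaute protein, stood at 84.0% ± 0.822 and 47.8% ± 0.149, and CAPN1, a calpain protease, at 53.5% ± 0.321 and 22.3% ± 0.255. FBXL20 and the RNA helicase gene DDX17 differed by -28.6 and -11.3 percentage points. Values were higher in K700E for MALAT1 (1.14% ± 0.172 and 3.74% ± 1.07), the base excision repair endonuclease APEX1 (6.05% ± 0.473 and 29.1% ± 1.33), LZTR1 (33.4% ± 11.3 and 66.5% ± 1.72), the ribosomal protein gene RPL17 (13.0% ± 3.72 and 34.3% ± 1.39) and PLAA (24% ± 5.66 and 70.8% ± 8.64). With only the most used of overlapping introns the difference of RPL17 was 44.3 percentage points, against 21.3 with all, and MALAT1 passed at 3.70 points (edgeR adjusted p = 0.0268). ITGB1BP1 stood at 12% and 0% in the WT samples and at 59.1% and 50% in K700E. The 0% is 0 of 14 overlaps, which would allow a share of up to 21.4% if each were a separate read. SF3B1 transcripts themselves were spliced in 75.6% ± 1.44 of read-intron overlaps in WT and 66.8% ± 4.49 in K700E, with an edgeR adjusted p of 1.00. The difference of -8.76 points was -5.59 without K700E replicate 2. The files do not tell the K700E allele from the wild-type one, so the labels could not be checked on SF3B1.

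None of the 10 gene lists with at least 5 measured members stood apart in efficiency, with camera adjusted p-values of 0.953 for every list, and no member passed over all genes tested or adjusted over the list alone. Among 23 measured genes with reported cryptic 3′ splice sites in SF3B1-mutant cells, 17 had lower and 6 higher efficiency in K700E, with a median of -4.84 percentage points against -2.58 over all genes. ZNF91, SLC3A2 and DLST had the smallest p of that list, with differences of 20.3, -8.61 and -16.3 points; that of SLC3A2 was -25.2 with only the most used of overlapping introns. Of 46 spliceosome genes 27 were lower and 19 higher: RBM17, which binds the SF3B1 subunit, stood at 54.8% ± 10.5 and 17.9% ± 4.56, HNRNPK at 42.1% ± 7.38 and 60.0% ± 0.0777 and CDC5L at 78.9% ± 15.7 and 97.6% ± 3.40. The CDC5L difference of 18.7 points was 29.9 without WT replicate 1 and 7.60 without WT replicate 2. Of 28 transcription elongation genes 19 were lower. Among these the pausing and elongation factor SUPT5H stood at 86.8% ± 1.48 and 54.8% ± 30.4, the histone chaperone subunit SUPT16H at 65.9% ± 32.3 and 26.1% ± 5.21 and ELL2 at 88.0% ± 0.153 and 60.2% ± 14.4, a difference of -27.8 points that was -16.1 with only the most used of overlapping introns and -17.6 without K700E replicate 2. The SUPT5H difference of -31.9 was -10.4 without K700E replicate 1 and -53.4 without K700E replicate 2, and that of SUPT16H, -39.8, was -17.0 without WT replicate 1 and -62.6 without WT replicate 2. Of 43 genes of replication stress and DNA damage 28 were lower, with RFC3 at 97.5% ± 1.72 and 89.4% ± 2.85, ERCC2 at 62.6% ± 14.8 and 24.5% ± 12.5 and TOP2A at 86.6% ± 6.32 and 73.4% ± 7.08 (-13.2 points, or -8.74 without WT replicate 1 and -8.19 without K700E replicate 1). Of 39 chromatin modifier genes 24 were lower, with SMARCA4 at 45.4% ± 8.99 and 26.0% ± 2.55, KMT2B at 81.0% ± 1.09 and 56.5% ± 9.17 and EP300 at 86.7% ± 1.75 and 68.5% ± 16.7 (-18.2 points, or -6.38 without K700E replicate 1 and -30.0 without K700E replicate 2). Median differences of the remaining lists were -4.73 points for 39 ribosomal protein genes, -0.526 for 20 haem, iron and erythroid genes and -0.479 for 19 snoRNA host genes. They were -5.49 for 23 mitosis genes and -6.43 for 20 oxidative phosphorylation genes. Camera compares members with the other genes: its direction was up, although the medians are below 0, for the spliceosome (median -2.51), erythroid and snoRNA host lists, with medians above that of all genes, and also for replication stress (-3.22) and mitosis, with medians below it. It was down for chromatin modifiers, with a median (-2.22) above that of all genes.

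Averaged over 6141 introns with at least 10 reads in every sample, efficiency was 65.5% and 63.6% in the WT samples and 61.8% and 63.8% in the K700E samples. The difference of -1.75 percentage points was within the spread between replicates (exact permutation test, two-sided, p = 0.667; 2 against 2 samples allow no p under 0.333). Efficiency was lower in K700E at 3137 introns, higher at 1952 and equal at 1052. Setting WT 1 and K700E 2 against WT 2 and K700E 1 gave a larger gap, 1.96 points, than genotype did. Mean efficiency differed by -3.70 points from WT 1 to K700E 1 and by 0.211 from WT 2 to K700E 2. It differed by -1.74 from WT 1 to K700E 2 and by -1.75 from WT 2 to K700E 1. Median efficiency over introns was 90.3% and 85.7% in WT and 80.0% and 85.1% in K700E, a difference of -5.45 points that separated the groups (exact permutation test, p = 0.333). Without WT replicate 1 the difference of means was -0.720 points and without K700E replicate 1 it was -0.778.

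Introns in different places of a gene differed far more than the genotypes did. First introns were spliced in 25.2% ± 0.0683 of reads in WT and 25.1% ± 0.503 in K700E, internal introns in 71.5% ± 1.57 and 69.5% ± 1.72 and last introns in 13.0% ± 0.918 and 12.9% ± 0.232 (SD over samples, n = 2 each). The low first and last values came in part from annotated alternatives that overlap: with only the most used of overlapping introns, they were 78.0% and 77.7% for first introns and 44.7% and 44.6% for last ones. By length, the quartile of shortest introns (1 to 403 nt) stood at 53.9% ± 1.16 in WT and 51.5% ± 0.580 in K700E, a difference of -2.41 points. It includes annotated gaps as short as 1 nt, as do the first, internal and last classes, and their weight in these means was not tested. The second quartile (404 to 1259 nt) stood at 68.1% ± 1.96 and 66.0% ± 1.04, the third (1261 to 3502 nt) at 74.8% ± 1.58 and 73.1% ± 2.29 and the longest (from 3503 nt) at 61.5% ± 0.834 and 60.6% ± 1.64. The shortest quartile and the 1541 introns whose position differs between transcripts (78.6% ± 1.68 and 76.2% ± 1.30) separated the groups, each with the smallest p possible (exact permutation test, p = 0.333). Single introns of a transcript stood at 4.60% ± 1.04 and 4.89% ± 0.130, or at 12.5% and 14.4% with only the most used of overlapping introns. Without K700E replicate 1 the difference of the longest quartile turned to 0.447 points, and that of the third quartile went from -1.63 to -0.160. The second quartile went from -2.06 to -0.561 without WT replicate 1. For introns of differing position, -2.47 became -1.20 without WT replicate 1 and -1.33 without K700E replicate 1. First, last and single introns themselves moved by -0.053, -0.032 and 0.289 points, so their planned contrasts with all introns (1.69, 1.71 and 2.04 points; exact permutation test, p = 0.333 each) are mainly the difference of all introns with its sign turned and show no rise in these classes.

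**Figure D2:**
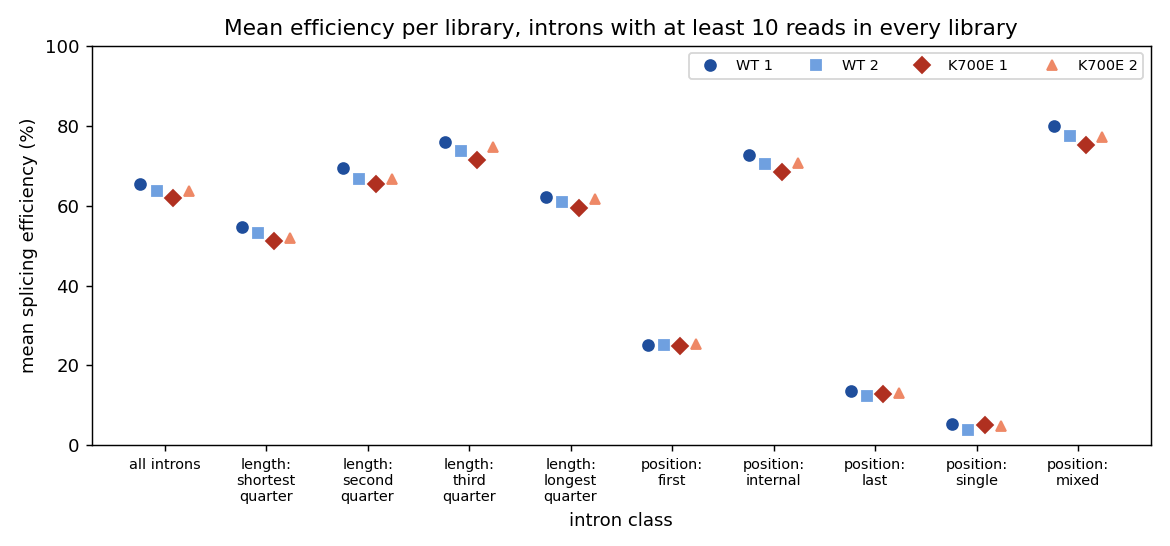
Mean splicing efficiency (vertical axis, percent) over all introns and in classes by length and by position in the transcript (horizontal axis), 1 point per library. Over all introns the WT libraries stood at 65.5% and 63.6% and the K700E libraries at 61.8% and 63.8%, while first introns stood near 25.2% in WT.

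Fewer groups of RNA 3′ ends had their median near the far end of the scale in K700E. These ends were taken to mark where RNA polymerase II stood, which was not checked. The files give, per row, the positions of at least 11 ends on a scale from 0 to 1. They name neither the rows nor the feature that the scale spans, so its ends are called the near (0) and far (1) end here. Rows with a median above 0.75 made up 4.78% (95% Wilson interval 3.96 to 5.76) and 5.44% (4.54 to 6.52) in the WT samples. In the K700E samples they made up 1.76% (1.26 to 2.45) and 2.59% (2.15 to 3.11). The groups did not overlap, and the difference of -2.94 points had the smallest p that 2 against 2 samples allow (exact permutation test, two-sided, p = 0.333). Rows with a median below 0.25 made up 7.87% and 5.54% in WT and 4.30% and 5.39% in K700E, so that the groups did not overlap (exact permutation test, p = 0.333) but WT replicate 2 and K700E replicate 2 lay within each other's intervals. In rows with at least 50 ends this near share was 6.43% and 4.45% in WT and 3.41% and 3.42% in K700E, and the far share 3.32% and 2.58% in WT and 0.602% and 0.906% in K700E (exact permutation test, p = 0.333 each). The standard deviation of row means across rows was 0.108 ± 0.00408 in WT and 0.0917 ± 0.00533 in K700E (n = 2 each). The deposited standard deviation of ends within a row averaged 0.264 in WT and 0.266 in K700E. It is not compared with the spread across rows, as the 2 may not be in the same units. The median of row medians was 0.460 and 0.480 in WT and 0.450 and 0.460 in K700E (exact permutation test, p = 0.667). The mean of row medians was 0.467 and 0.489 in WT and 0.460 and 0.462 in K700E, and rows with a median under 0.5 made up 58.3% and 52.2% in WT and 62.2% and 61.1% in K700E, 6.37 points more. Both lie closer to the near end in K700E, with the smallest p possible (exact permutation test, p = 0.333 each). The intervals cover counting error only. Rows numbered 2174 and 2021 in WT and 1929 and 4209 in K700E, with 412065, 292576, 223997 and 608736 ends in the same order.

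**Figure D3:**
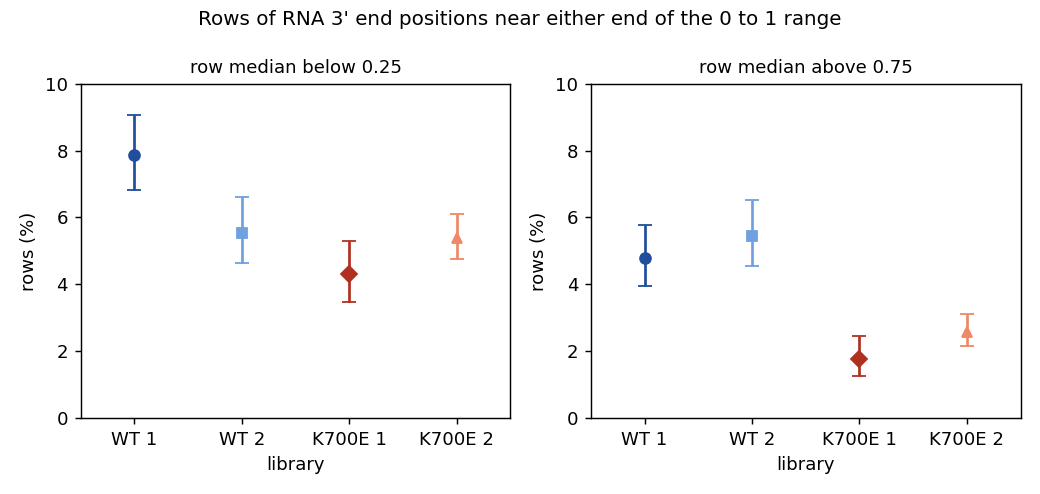
Share of rows (vertical axis, percent) whose median 3′ end position lies below 0.25 (left) or above 0.75 (right), per library (horizontal axis), with 95% Wilson intervals as bars. On the right the WT libraries stand at 4.78% and 5.44%, above the K700E libraries at 1.76% and 2.59%.

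Nascent reads per gene, counted over the most covered intron of each gene, differed for no gene by edgeR's quasi-likelihood test (0 of 2979 genes; 168 with an unadjusted p under 0.05; DESeq2 0). Without WT replicate 2 the same test called 165 genes and without WT replicate 1 it called 8. Lowest in K700E by p were LINC00624, a long non-coding RNA, and genes for the dynein subunit DYNC1LI2, the cohesin subunit RAD21, the lysosomal protein precursor PSAP and RIC8A. LINC00624 had 16 and 20 counts in WT and 0 and 0 in K700E, at least 3.04-fold lower against a limit of 3 counts per library. PSAP had 183 and 332 counts in WT and 16 and 32 in K700E (log2 fold change -2.63 ± 0.70, standard error), and RAD21 had 71 and 19 against 2 and 3 (-3.28, or -2.16 without WT replicate 1). The log2 fold changes of DYNC1LI2 and RIC8A were -2.95 and -2.80. Higher in K700E were VEPH1, with 2 and 2 counts in WT and 14 and 25 in K700E (log2 fold change 4.01 ± 0.75), the replication factor gene MCM10, with 3 and 6 against 8 and 25, and the cell cycle phosphatase gene CDC25A, with 1 and 0 against 7 and 11. NXF2 (1 and 2 against 6 and 19) and ZNG1C (1 and 3 against 7 and 20) have near-identical copies and are uncertain. The edgeR adjusted p-values of these 10 genes lay between 0.775 and 0.815. Left without WT replicate 1 the same test called VEPH1 (edgeR adjusted p = 0.0157) and PSAP (0.0111) among them. Without WT replicate 2 it called all but LINC00624 and CDC25A, from RAD21 (edgeR adjusted p = 0.000135) and VEPH1 (0.00160) to PSAP (0.0476), and without K700E replicate 1 or 2 it called 0 genes. SF3B1 had 179 and 39 counts in WT and 16 and 18 in K700E, a log2 fold change of -1.72 ± 0.81 (edgeR adjusted p = 0.815) that was -0.392 without WT replicate 1 and -2.46 without WT replicate 2 (edgeR adjusted p = 0.0162).

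Of the lists, snoRNA host genes were lower in nascent reads in K700E by camera (adjusted p = 0.0462), with 15 of 19 members lower, 4 higher and a median log2 difference of -0.65. That median was -0.182 without WT replicate 1 and -0.657 without WT replicate 2. It was -0.433 without K700E replicate 1 and -0.917 without K700E replicate 2. The adjusted p was 0.982 with an estimated correlation, and with all samples no member passed over all genes tested or adjusted over the list alone. EEF2, HSPA8, SNHG1 and SNHG5 had the smallest p of the list, and the WT mean of each came mainly from replicate 1. HSPA8, a constitutive heat shock protein gene, had 409 and 102 counts in WT and 17 and 65 in K700E, and SNHG1 had 350 and 57 against 10 and 58. The log2 fold changes of EEF2, HSPA8, SNHG1 and SNHG5 were -1.82, -1.94, -1.94 and -1.86, and without WT replicate 1 they were -1.04, -0.740, -0.227 and -0.00100. Without WT replicate 2 they were -2.34, -2.62, -2.73 and -2.66, and all 4 passed (edgeR adjusted p from 0.00789 to 0.0165). The list's camera adjusted p was 0.724 without WT replicate 1, 0.000540 without WT replicate 2, 0.161 without K700E replicate 1 and 0.0235 without K700E replicate 2. The medians of the other lists below, except ribosomal protein genes, turned sign with at least 1 of the samples left out. Of 30 genes of replication stress and DNA damage 20 were higher (median 0.24, adjusted p = 0.145) and of 14 erythroid genes 11 were lower (median -0.64, adjusted p = 0.143); the erythroid list passed without WT replicate 1 (camera adjusted p = 0.00252) and without K700E replicate 2 (0.00427), but its median turned to 0.0999 without K700E replicate 1. Of 31 ribosomal protein genes 23 were lower (median -0.27, adjusted p = 0.159; -0.58 and 0.0379 by camera without K700E replicate 2, -0.00855 and 0.816 without WT replicate 1), and of 30 chromatin modifier genes 20 were lower (median -0.41, adjusted p = 0.292). Medians were -0.20 for 17 mitosis genes (adjusted p = 0.292), 0.10 for 14 genes with reported cryptic sites, -0.08 for 37 spliceosome genes and 0.00 for 14 oxidative phosphorylation genes (camera adjusted p = 0.958 each). For 19 elongation genes it was 0.12 (adjusted p = 0.961), with the test on the lower side.

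Markers of other cells were scarce. Epithelial markers, listed because the labels call the line epithelial, took 0.0170% and 0.0164% of counts in WT and 0.0126% and 0.0123% in K700E. Markers of other blood lineages took 0.0204% and 0.0877% in WT and 0.0779% and 0.185% in K700E, almost wholly the leukocyte phosphatase gene PTPRC with 28, 93, 33 and 161 counts. Too few members of either list were measured to be tested.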

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

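All alternatives were planned except the dispersion setting, the crossed pairing, overlapping introns counted once, ratios above 1 kept or left out, MALAT1 left out, rows weighted by ends and rows of at least 50 ends, which were chosen after seeing the data. Introns past the threshold numbered 5 as reported, 0 with DESeq2, 0 with limma, 126 with Fisher's exact test on pooled reads, 1 with an estimated dispersion and 4 to 6 with other read minimums, with ratios above 1 left out or with overlaps counted once. Leaving out 1 sample gave 0 (without K700E replicate 2) to 10 (without WT replicate 2), with 1 group then held by a lone sample that is assumed to vary like the others. Genes past the threshold for efficiency numbered 0 as reported, 1 with DESeq2, 1 with overlaps counted once, 991 with Fisher's exact test and 0 otherwise. For nascent reads they numbered 0 as reported, 1 with no filter, and 0 to 165 (without WT replicate 2) with a sample left out. Lists called on nascent reads numbered 1 as reported, 0 with an estimated correlation, 0 with fry and 0 to 3 with a sample left out; 0 lists were called on efficiency under any setting. The cause was not tested, save that fewer samples enter where 1 is left out. Same-numbered samples did not deviate together (correlations of -0.161, -0.061 and -0.014 for introns, genes and nascent reads). For efficiency, opposite-numbered samples did so weakly. WT 1 and K700E 2 both stood above WT 2 and K700E 1 at 22.7% of introns and below at 9.90%. Both WT samples stood above both K700E samples at 19.9% and below at 9.19%. Whether opposite-numbered samples share a batch stays open. With the replicate block 3 introns and 0 genes passed for efficiency. For nascent reads 2 genes passed: VEPH1 (edgeR adjusted p = 0.01001) and MALAT1 (7.11e-12, log2 fold change -1.76), the latter named after its values were seen. The crossed pairing gave 5 introns and 0 genes.

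The difference of means over introns stayed negative under every alternative, from -0.720 to -3.09 points, as did that of the median of row medians, from -0.005 to -0.025; the difference of medians over introns was -5.45. Class differences near 0 changed sign. First introns (-0.053 as reported) gave 0.608 at 20 reads, 5.32 as a pooled share, 0.214 with thinned reads and -0.459 to 0.251 with a sample left out. Last introns (-0.032) gave 0.0690 at 20 reads, -1.48 at 5, -2.78 at 1, -1.19 as a pooled share, 0.106 with thinned reads and -0.800 to 0.631 with a sample left out. Single introns (0.289) gave -0.414 at 5 reads, -0.539 at 20, -0.398 at 1, 1.96 as a pooled share, 1.86 with overlaps counted once and -0.399 to 1.28 with a sample left out. The longest quartile ranged from -2.08 to 0.447, MAT2A intron 6 from -31.5 to 9.58 and the HNRNPA2B1 intron from -9.60 to 37.5 with a sample left out; the cause was not tested. Entries within a fixed distance and distinct positions were not run, as rows give neither. The test is limited. With simulated counts of equal spread at every intron, it called 2% of introns changed by a log2 odds ratio of 2. It called 32% of those changed by 4.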

Other observations

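The tests of this part were all chosen after the results were seen, and each was run on the data that showed the pattern.

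Alternative 3′ splice sites were compared through introns that share a 5′ splice site. The total of a 5′ splice site was added once per alternative site, and sites closer than about 12 nt repeat the same reads. The shares below are therefore not shares of distinct junction reads. At 202 annotated sites 12 to 40 nt upstream of the most used site, the share of junction reads was 14.5% and 11.5% in WT and 13.9% and 16.7% in K700E (exact permutation test, p = 0.667). At 304 sites 41 to 200 nt downstream it was 12.2% and 12.7% in WT and 14.8% and 14.2% in K700E, and at 167 sites 12 to 40 nt downstream 13.1% and 15.0% against 16.1% and 16.9%. Both downstream windows separated the groups with the smallest p possible (exact permutation test, p = 0.333 each). The most used site was chosen on junction reads summed over all libraries, 812749 and 624501 in WT and 215427 and 490130 in K700E. As WT supplied most of them, this choice can by itself lower the alternative share in WT. The separation therefore does not show a shift in site use. At 247 sites 41 to 200 nt upstream the means were 16.0% ± 3.003 and 15.7% ± 0.575 (SD, n = 2 each).

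Of genes listed for cryptic 3′ splice sites in SF3B1-mutant cells, 2 were compared at an annotated site in the 12 to 40 nt upstream window: DLST, of the 2-oxoglutarate dehydrogenase complex (19 nt upstream), and ENOSF1 (15 nt). WT libraries had 0 of 4 and 0 of 8 junction reads there, and K700E libraries 2 of 4 and 2 of 11. A hypothesis is that K700E raised the use of these sites; Fisher's exact test on pooled reads, which compares these libraries only, gave a two-sided p of 0.106. The difference rests on 4 reads, with the most used site chosen as above, may be chance, and stays open.

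ADGRV1 has 3 called introns, and a further one that did not pass fell by as much as intron 24 (a difference of -16.2 points). A long read can cover several of these introns, so the calls may share reads and are not independent. A loss of splicing along the whole gene in the K700E libraries is argued against by the 61 introns other than the 3, whose median difference was 0.0 points. That median does not speak to a smaller fall in the stretch around the 3. Differences lay between -16.2 and 0.0 points from intron 28 to intron 35, and between -5.13 and -1.35 from intron 37 to intron 42. Those of introns 25 and 26 were 3.13 and 3.85 points. A local loss beyond the 3 introns thus stays open. Skipping of a neighbouring exon, as the whole cause, would lower a neighbouring intron as much as the intron itself. This holds only if a skipping read counts over both introns, which could not be checked, as read assignment is not given. Over all pairs of a WT and a K700E library, the lowest difference of a neighbour was -20.9 points beside intron 27 and -19.5 beside intron 36, while the differences of these introns themselves were -43.4 and -39.2 points or lower in every pair. On that condition this argues against skipping as the whole cause at these introns, and a part in it stays open. The bound of this test was revised after the values were seen; an earlier bound, on a part of the fall, left all 3 introns open. The difference of intron 24 was -15.1 points or lower in every pair, but that of its neighbour, intron 25, was -28.9 in 1 pair (standard error of its difference 22.9 points), so skipping cannot be ruled out there. Use of a nearby site that the annotation lacks could also lower these values without any intron being kept, and 0 annotated alternative sites within 200 nt had reads, so the tables cannot separate it from retention. Genotype remains open as an explanation that 2 samples per group do not separate from other differences between the cell lines or libraries.

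Fewer rows of 3′ ends had a median above 0.75 in K700E, and rows with a median below 0.25 were also fewer, though the groups lay closer there. Noise from rows with few ends would be expected to fade where ends are many. In rows with at least 50 ends both shares fell, and the difference narrowed from -2.94 to -2.20 points. The WT share was there 3.91 times the K700E share, against 2.35 times in all rows, and the groups did not overlap. The difference thus did not rest on rows with few ends alone, and a ratio of shrinking shares does not show that such noise has no part. That the libraries list other genes or regions may be a source of the difference: K700E replicate 2 has 2.18 times as many rows as K700E replicate 1, and rows without names cannot be matched. Genotype and row content cannot be told apart here.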
